A study of Homo sapiens with 9 samples.

How the data were processed

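EGR1 binding was profiled by chromatin immunoprecipitation with sequencing (ChIP-seq) in BJ-hTERT-BRAF-V600E, an immortalised human fibroblast line in which doxycycline switches on the BRAF V600E oncoprotein. EGR1 is a zinc finger transcription factor induced by MAP kinase signalling. Per the labels, 9 libraries fell into 3 groups of 3: proliferating cells given ethanol, cells induced with doxycycline at 1000 ng/mL, and induced cells also given the glucocorticoid clobetasol at 2 nM, each for 24 h. Source labels name DMSO for the 2 groups without clobetasol. Titles name DMSO for all 3 groups, and whether the clobetasol group also received it is not settled by the sources used here. The labels do not say whether the 3 libraries of a group came from separate cultures.

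Per the submitters' processing notes, the upstream tools included bcl2fastq, cutadapt 1.15, FastQC 0.11.5, BWA, SAMtools 1.3.1 and MACS2 2.1.1.20160309, with the hg19 build. The settings of the peak caller are not given in the sources used here. Per the file's peak names, the authors pooled replicates 1, 2 and 3 of a treated group and used the pooled proliferating EGR1 ChIP libraries as the control. Per the labels, the library names given for proliferating replicates 2 and 3 carry the same sample name, so whether the control pool held 3 distinct samples is not settled by the sources used here. Each of the 2 deposited lists therefore holds sites where the treated pool exceeded proliferating cells, and no value per replicate. The authors' fold enrichment in each row is a ratio of the treated pileup to the local control level at the summit. The deposited −log10 p and −log10 q values are those of the summit, and the lowest −log10 q was 5.00228 in the induced list and 5.00012 in the clobetasol list. The deposited score was the whole part of 10 times the −log10 q in every row. Peak numbers ran to 52393 and 26677, above the 16285 and 12340 peaks listed. Peaks may therefore have been removed after calling, which is not recorded in the sources used here. A site called lost, or without a peak, is only known to lack an overlapping peak in the deposited list. Folds and q values given for single peaks are the authors' and were used to describe, rank or filter peaks within 1 list.

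The overlap rule, the tests on overlap, fold and chromosome, and the rule for named sites were set before the data were examined. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Observed overlap was compared with 100 random circular shifts of the other list within each chromosome (one-sided), for which the smallest possible p is 0.0099. Median folds of retained and lost peaks were compared by a two-sided permutation test with 100000 resamples. Retention was compared between the 20% of induced peaks with the highest and the lowest fold and on each of 22 autosomes with Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the autosomes. Intervals of shares are 95% Wilson intervals. They cover counting error only.

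The named sites were the 10 peaks of highest −log10 q in each list and the 5 per list of highest −log10 q without overlap in the other list, on chromosomes 1 to 22 and X. Many of these were repeat-like, as defined next. The peaks of highest q or fold without repeat-like sites, and the sites of largest change, were therefore added after their values were seen. A site was called repeat-like when it lay outside chromosomes 1 to 22 and X or had a control level over 5 times the lowest of its list. No repeat annotation was used, so the label does not show a repeat. A site of strong EGR1 signal in proliferating cells can carry it too. For sites called higher or lower, either list counted. Sites are named by position, counted from 1 in hg19. The promoter, motif and gene-list tests that had been planned were not run, because no genome or annotation of hg19 was used here and the reference gene table is of another build. Nearest genes are therefore not given.

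A comparison of the pileups was added after the files were seen. The fold is the treated pileup plus 1 over the control level plus 1, and the −log10 p is a Poisson tail of the same quantities, so both could be solved for each peak. The treated pileup came out within 0.05 of a whole number of fragments for 99.6% of induced and 99.5% of clobetasol peaks, where chance would give 10%. Control levels fell on multiples of 0.552 in the induced list and 0.670 in the clobetasol list, the factor that scales the proliferating pool to each treated pool. The ratio of these factors, 1.21, was taken as the depth of the clobetasol pool relative to the induced pool. At 397 shared sites with the same summit, the proliferating fragments recovered from the lists had a median ratio of 1.00, and 68.5% were within 1%. Fragments in the clobetasol pool were divided by the depth ratio and compared with those in the induced pool by a two-sided exact binomial test with Benjamini-Hochberg adjustment at 0.05. That test compares 2 pools, not the conditions, since the spread between replicates is not known. The depth of single libraries is not known. Read totals were not used here. An input or spike-in control was not used here, so the yield of the immunoprecipitation was not measured.

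The retention that depth and counting noise would allow was simulated with 100 Poisson draws per peak at the depth of the clobetasol pool, with the pileup unchanged or lowered. The simulation starts from the listed pileups, which lie above their long-run mean at peaks picked for passing a threshold, and so overstates retention of weak peaks. Losses among strong peaks were also set against the number expected, by a negative binomial distribution that carries the counting error of both pools, at the median excess ratio of those peaks. On simulated lists, the recovery returned the fragment number to within 0.5 at 100% of the 16285 induced and 12340 clobetasol peaks. The binomial test, run on 16285 simulated sites, passed 86.0% of 100 sites raised 2-fold, 47.0% of 100 sites lowered 2-fold and 0.00622% of 16085 unchanged sites. Alternatives were stricter q and fold thresholds, 2 other overlap rules, lists of equal length and lists without repeat-like sites. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.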

Results

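EGR1 ChIP-seq was carried out in BJ-hTERT-BRAF-V600E fibroblasts in 3 groups of 3 libraries: proliferating cells, cells in which BRAF V600E was induced for 24 h with 1000 ng/mL doxycycline, and induced cells labelled as given 2 nM clobetasol for 24 h. Induction of BRAF V600E leads such fibroblasts into senescence, a lasting arrest of proliferation, and clobetasol is a potent agonist of the glucocorticoid receptor. Each treated pool was compared with the pool of proliferating libraries, so every value below rests on 1 pool per group and has no replicate spread. The median peak summit held 64 fragments in the induced pool (interquartile range 44 to 106) and 75 in the clobetasol pool (52 to 120). The clobetasol pool was the deeper by a factor of 1.21.

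The first comparison asked where EGR1 occupancy rose when BRAF V600E was induced. Induction gave 16285 sites above proliferating cells, covering 8.67 Mb of hg19, with a median fold of 3.64 (interquartile range 3.12 to 4.37). Gains were spread over the genome, with 15750 sites on autosomes. Fold exceeded 5 at 2128 sites and was under 2 at 242. Most gains lay where proliferating cells had a raised control level: over 2 times the lowest of the list at 66.3% of sites. The control level was at the lowest at 309. The 66.3% include 2911 sites over 5 times the lowest. Without an input control, EGR1 signal in proliferating cells could not be told from other background there.

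Among chromosomes 1 to 22 and X, the strongest gains by q with folds of several times were on chromosomes 7, 17, 13 and 19. The site at chromosome 7, 102256967 to 102257490, had the highest −log10 q of the 10 named sites (324.5), with a fold of 6.01 and 784 fragments. A neighbouring site at chromosome 7, 102157979 to 102158534, had a fold of 5.26. On chromosome 17, the sites at 79008508 to 79009018 and at 1106535 to 1106978 had folds of 6.07 and 5.82. The site at chromosome 13, 80915006 to 80915574, reached 7.47. On chromosome 19, the sites at 13273799 to 13274239 and at 48825101 to 48825528 reached 7.95 and 6.98. The other 3 of the 10, on chromosomes 10 and 19, had folds of only 1.305 to 1.640 on control levels over 400 times the lowest. All 10 sites had a control level over 5 times the lowest.

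Outside repeat-like sites, gains were ranked by fold, which favours sites with a low control level. The largest fold of the list, 14.0, was at chromosome 7, 73508462 to 73509398, with 183 fragments. It was followed by chromosome 12, 13500108 to 13500715 (fold 11.8, 252 fragments), chromosome 1, 205418927 to 205419442 (fold 11.8, 115 fragments), and chromosome 22, 38301686 to 38302958 (fold 11.7, 127 fragments). A site at chromosome 5, 158247257 to 158247761, had a fold of 11.5 where proliferating cells were at the lowest control level.

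Gains were densest on the gene-rich chromosomes. Chromosome 19 held 18.0 induced sites per Mb, chromosome 22 held 12.3, chromosome 17 held 12.0 and chromosome 16 held 8.75. The gene-poor chromosomes 4, 13 and 18 held 3.06, 3.21 and 3.39. The densest 1 Mb window outside repeat-like sites was chromosome 19, 18000001 to 19000000, with 43 sites, followed by chromosome 7, 100000001 to 101000000, with 42.

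**Figure D1:**
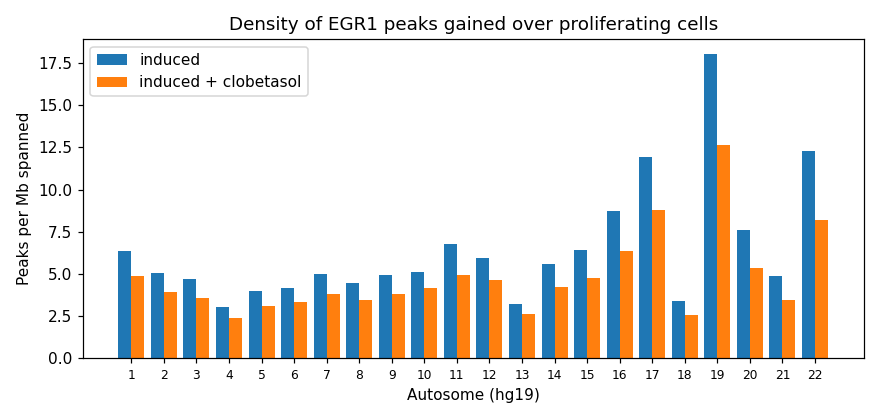
Bars give peaks per Mb of the spanned length of each autosome (hg19), for induced cells and for induced cells given clobetasol, each against proliferating cells. Chromosome 19 is highest with 18.0 and 12.6 peaks per Mb, and chromosome 4 is lowest with 3.06 and 2.40.

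The second comparison asked where EGR1 occupancy rose when the oncoprotein was induced in the presence of clobetasol. Induced cells given clobetasol had 12340 sites above proliferating cells, covering 5.01 Mb, with a median fold of 3.16 (interquartile range 2.75 to 3.68). Fold exceeded 5 at 468 sites and was at least 3 at 7281. Chromosomes 19, 17, 22 and 16 again held the most sites per Mb (12.6, 8.82, 8.18 and 6.36).

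The site of highest −log10 q on chromosomes 1 to 22 and X was at chromosome 2, 241190577 to 241191192, with a fold of 8.67 and 484 fragments. The site at chromosome 19, 47538762 to 47539237, had a fold of 6.51 and 525 fragments. Several of the strongest induced sites were also among the 10 named here: the listed folds were 4.58 and 3.95 at the chromosome 7 pair, 6.44 at the chromosome 13 site, and 4.48 and 4.83 at the chromosome 17 sites. The largest fold of the list outside repeat-like sites, 11.7, was at chromosome 3, 105511194 to 105511689, with 167 fragments. The next, 11.4, was at chromosome 14, 95855949 to 95856436, with 101 fragments.

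The third comparison asked how far clobetasol changed the sites gained on induction. With clobetasol, 10429 of the 16285 induced sites had an overlapping peak (64.0%, 95% Wilson interval 63.3 to 64.8), and 5856 had none. The clobetasol list was 24.2% shorter although its pool was deeper. In the other direction, 10657 of 12340 clobetasol sites overlapped an induced site (86.4%) and 1683 did not. Random shifts gave a median of 0.568% and 0.721%, with p = 0.0099 by this permutation of positions in both directions, the smallest that 100 shifts can give. Both lists share the proliferating libraries as control, so part of this overlap may come from the shared control and it is not read as a shared effect.

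Sites lost with clobetasol had lower folds, a direction that the threshold of the clobetasol list by itself would give under a uniform fall. Sites with no clobetasol peak had a median fold of 3.34, against 3.91 for retained sites, a difference of 0.574 (permutation p = 1e-05, the smallest that 100000 resamples can give). The difference was 0.341 at −log10 q of at least 10 and 0.878 at a fold of at least 3 in both lists. They held a median of 44 fragments against 86. Of the 20% of induced sites with the lowest fold, 48.7% were retained, and of the 20% with the highest, 90.1%, a difference of 41.4 percentage points (Fisher's exact p = 1.34e-306, over sites, which are not independent replicates). It was 24.8 points at −log10 q of at least 10, 23.8 with lists of equal length and 68.1 at a fold of at least 3. By the level in proliferating cells, retention was 36.6% where the control level was in its lowest 20% and 90.0% in its highest 20%. Among strong sites, with −log10 q of at least 20, retention was near its ceiling (94.5% in all), so a difference in points had to be smaller. From the lowest to the highest 20% by control level, it was 91.0%, 94.1%, 95.3%, 97.4% and 94.7%. At retained sites, the depth-scaled pileup with clobetasol was a median 0.697 of that without it in the lowest class and 0.814 in the highest. These pileups include the control level. An equal proportional fall in the excess over control would thus also give a ratio nearer 1 where that level is high, so no difference by control level is read from them. Of the 309 sites at the lowest control level, 81 were retained (26.2%, 95% Wilson interval 21.6 to 31.4).

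**Figure D2:**
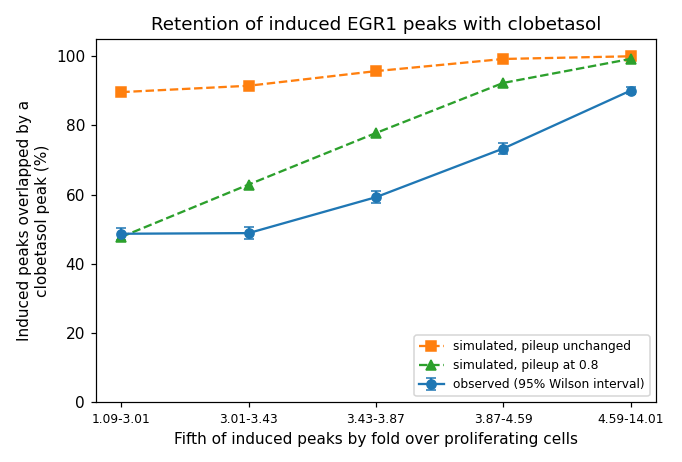
The y axis gives the percentage of induced peaks overlapped by a clobetasol peak, over 5 equal classes of fold on the x axis, with 95% Wilson intervals on the observed points. Observed retention rises from 48.7% to 90.1%, while simulated retention at an unchanged pileup runs from 89.6% to 100.0% and at 0.8 of the pileup from 47.8% to 99.2%.

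Depth and counting noise alone would have retained more sites. In simulations at the depth of the clobetasol pool, an unchanged pileup retained 95.2% of induced sites, against 64.0% observed. Among the 11103 sites with −log10 q of at least 10, 80.5% were retained against 99.8% simulated. The 5 named sites without a clobetasol peak were all repeat-like, with control levels from 8.76 to 5863 times the lowest. Outside repeat-like sites, the strongest lost sites were at chromosome 17, 27895430 to 27895850 (fold 5.55), chromosome 20, 48598945 to 48599855 (fold 5.18), chromosome 4, 88744185 to 88744506 (fold 5.98), and chromosome 14, 101543752 to 101544146 (fold 5.94). Of the 5 named clobetasol sites without an induced peak, 3 were repeat-like. The others were at chromosome 1, 144707628 to 144708057 (fold 4.59, 185 fragments), and chromosome 17, 43033389 to 43033963 (fold 9.07, 88 fragments). The control level was 4.996 times the lowest at the chromosome 1 site, just under the bound for repeat-like sites, and only 1.11 times at the chromosome 17 site.

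No autosome stood out in the share of induced sites lost. Fisher's exact test with Benjamini-Hochberg adjustment passed 0 of 22 autosomes, and 1, chromosome 12, had an unadjusted p under 0.05 (p = 0.0188, adjusted p = 0.414, 68.0% retained). At −log10 q of at least 10 in both lists, chromosome 18 passed the same Fisher's exact test, with 95 sites retained and 87 lost (52.2% retained, adjusted p = 0.0301). Over all induced sites, 63.8% were retained with that bound in both lists.

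The comparison of pileups at shared sites was added after the lists were seen. At the 10429 shared sites, the depth-scaled pileup with clobetasol was a median 0.799 of that without it (interquartile range 0.707 to 0.911), and it was lower at 87.4% of sites. The 5856 sites without a clobetasol peak have no ratio, so the median leaves out sites that fell below the threshold of that list, which raises it. It also leaves out clobetasol sites without an induced peak, and every site had to pass in the induced list, which lowers it. The median ratio was 1.00 among the 20% of induced sites with the lowest q, of which 23.4% were retained. Among the 20% with the highest q, of which 98.4% were retained, it was 0.740. The median lay between 0.759 and 0.823 on every autosome, and resampling of autosomes gave a 95% interval of 0.791 to 0.802. The binomial test called 2356 sites lower (22.6%) and 40 higher (0.384%). Without repeat-like sites it called 1171 of 7699 lower and 12 higher. At −log10 q of at least 20 in the induced list, 2865 of 5800 sites were lower and 16 higher. With that bound in the clobetasol list, 1346 of 3892 were lower and 40 higher. Against 1 common factor of 0.735 on the excess over the control level, in place of equality, 25 sites were lower and 94 higher. Summits lay a median of 10 bp apart, and 96.1% were within 100 bp. These values compare 1 pool with 1 pool, so no difference could be set against the spread between replicates, and the yield of the immunoprecipitation was not measured.

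**Figure D3:**
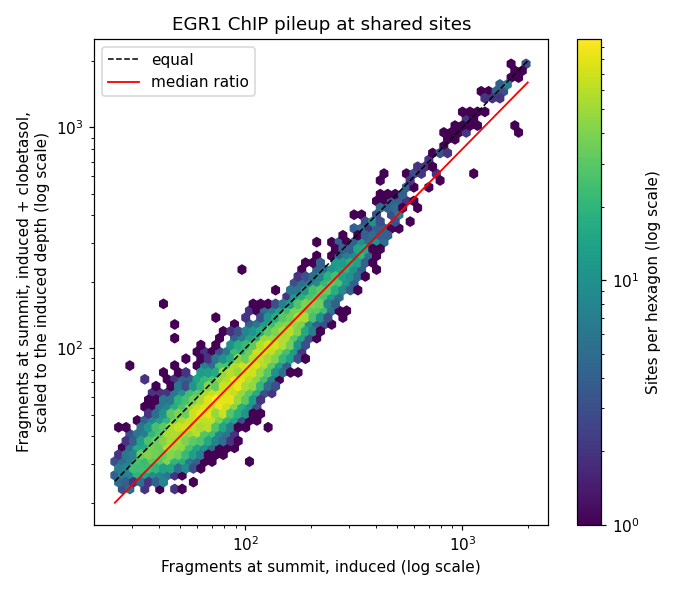
Each hexagon counts shared sites by fragments at the summit in the induced pool (x axis, log scale) and in the clobetasol pool scaled to the induced depth (y axis, log scale), for sites with fewer than 2000 scaled fragments. Most sites lie below the dashed line of equality, along the solid line at the median ratio of 0.799.

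The size of the decrease showed no trend with fold that held however sites were picked. Over equal classes of shared sites by fold in the induced list, the median ratio went from 0.937 at the lowest folds to 0.698 at the highest, but by fold in the clobetasol list it went from 0.775 to 0.835. With both pools used for the classes it went from 0.875 to 0.750. The site of largest fold, chromosome 7, 73508462 to 73509398, went from 183 fragments to 109 in the deeper clobetasol pool, a ratio of 0.490 (exact 95% interval 0.383 to 0.625). Of the 10 sites with the largest induced fold that were not repeat-like, all had ratios below 1, and the interval excluded 1 at 6. Picked in the clobetasol list, the 10 sites of largest fold included 9 with an induced peak, of which 0 had intervals below 1 and 3 above. On chromosomes 1 to 22 and X, all 10 sites of highest q in the induced list had intervals below 1, with ratios from 0.690 to 0.946, and of the 10 in the clobetasol list, which were all repeat-like too, 7 had intervals below 1 and 1 above. Outside repeat-like sites, the 10 of highest q in the induced list had 8 intervals below 1 and 0 above, and those in the clobetasol list 2 below and 3 above.

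Some sites fell much further. The site at chromosome 1, 224803377 to 224805464, went from 104 to 37 fragments, a ratio of 0.293 (0.196 to 0.430, adjusted p = 6.97e-09 by the exact binomial test). At chromosome 11, 76400285 to 76400760, the ratio was 0.345 (0.245 to 0.481). It was 0.404 at chromosome 12, 49371113 to 49372181, where summits lay 246 bp apart, and 0.449 at chromosome 3, 9974334 to 9974838. In all, 56 shared sites had a ratio below 0.5, and how many of these counting error around the general decrease would give was not computed. Of the 2356 lower sites, 1364 were outside repeat-like regions in both lists, with a median ratio of 0.620, a value taken over sites picked for being low. Those calls are against equality, not against the general decrease. Against 1 common factor of 0.735 on the excess over the control level, 25 shared sites were lower and 94 higher.

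A small group of sites had a higher pileup with clobetasol. Of the 40 higher sites, 17 were outside repeat-like regions in both lists, with ratios from 1.43 to 2.77, and 12 passed when only sites outside such regions were tested. At chromosome 14, 95855985 to 95856436, fragments went from 30 to 101, a ratio of 2.77 (1.83 to 4.32, adjusted p = 2.42e-05 by the exact binomial test). At chromosome 1, 144983008 to 144983316, they went from 95 to 285, a ratio of 2.47 (1.95 to 3.15), with a control level just under the bound for repeat-like sites. The site at chromosome 3, 105511260 to 105511651, rose from 72 to 167, a ratio of 1.91 (1.44 to 2.55). Weaker calls were those at chromosome 7, 47797088 to 47797801 (ratio 1.78, adjusted p = 0.0121 by the exact binomial test), and chromosome 3, 196415269 to 196415517 (ratio 1.75, adjusted p = 0.00666). Neither passed a one-sided form of the test adjusted over all shared sites, while the sites just named on chromosomes 14, 1 and 3 with larger ratios did. The largest ratio, 3.66 at chromosome 7, 148824451 to 148824677, joined summits 584 bp apart, with a control level over that bound in the clobetasol list, so it need not describe 1 site.

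**Figure D4:**
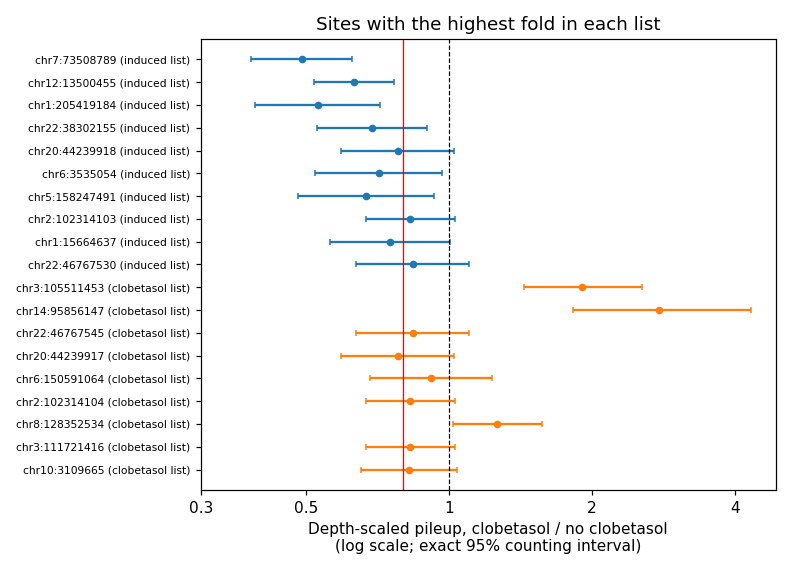
Points give the depth-scaled pileup with clobetasol over that without it (x axis, log scale) at the sites of highest fold in each list outside repeat-like regions, with exact 95% counting intervals, and the solid line marks the median of 0.799 over shared sites. All 10 sites of the induced list lie below 1, and 3 sites of the clobetasol list have intervals above 1: those on chromosomes 14 and 8, and the site at 105511453 on chromosome 3.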

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

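The tests on contigs in this part were chosen after the result was seen. Peaks were listed outside the assembled chromosomes, which the comparisons by chromosome did not use. The unplaced contig that carries ribosomal DNA, the genes for the large ribosomal RNAs, held 19 peaks in the induced list and 7 in the clobetasol list, over 29488 and 3326 bp. Its 3 strongest shared sites fell with clobetasol, with depth-scaled ratios of 0.515, 0.564 and 0.556. A candidate explanation is that reads from many repeat copies were placed on 1 reference copy. The median control level there was 70.3 times the lowest of the induced list, as such stacking predicts. Stacking would raise the proliferating pool too, so this level does not show why the sites exceeded proliferating cells. Folds in the induced list were 3.99, 4.02 and 3.22 at those 3 sites, against a median of 1.56 over the 19 peaks. Why the ratio was lower there with clobetasol was not tested, and no biological explanation was tested.

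Over all contigs outside the assembled chromosomes, 142 peaks were listed with induction and 95 with clobetasol. They were of different kinds. The 65 induced peaks on alternate haplotype contigs had a median control level of 1.53 times the lowest, which stacking of repeats does not predict. The 58 on the remaining contigs, without the one with ribosomal DNA, had a median of 38.2 times the lowest, as stacking predicts, with 86.2% over 5 times.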

How the results depend on the processing

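Alternatives on pileups, simulated retention and repeat-like sites were added after seeing the data. Of 57 alternative values over 11 results, 46 kept their direction and call or stayed close in size, none reversed or lost significance, and 11 moved. The tally leaves out a −log10 q of at least 5, which removed no peak and tests nothing. Part of it could hardly have come out otherwise. The overlap p was at its smallest possible value in every setting, and the threshold of the clobetasol list by itself would give the direction of the fold results. The share of induced sites retained ran from 46.0% (fold of at least 3 in both lists) to 76.5% (lists of equal length), and the share of clobetasol sites in the induced list from 72.99% to 86.95%. The median pileup ratio ran from 0.735 (excess over the control level) to 0.816 (−log10 q of at least 20 in the clobetasol list). A fold of at least 3 left 7281 clobetasol peaks against 13089 induced ones. At −log10 q of at least 10, the number of autosomes past the threshold moved from 0 to 1. The cause was not tested. Lower sites numbered 1346 of 3892 at −log10 q of at least 20 in the clobetasol list and 1171 of 7699 without repeat-like sites. They numbered 2865 of 5800 at −log10 q of at least 20 in the induced list, against 2356 of 10429 in the main setting. Higher sites numbered 16 of 5800 at −log10 q of at least 20 in the induced list and 12 of 7699 without repeat-like sites. The counts rest on different numbers of tested sites. The cause was not tested for these either. Simulated retention was 87.97%, 75.99% and 60.01% at 0.9, 0.8 and 0.7 of the pileup, 78.67% at a common factor on the excess, and 99.82% at −log10 q of at least 10.

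No paired analysis was possible because the authors pooled the libraries within each list and the lists hold no value per replicate. Leaving out each replicate was not possible for the same reason. Alternatives on promoter windows, motif windows and definitions, gene lists and GC strata were not run.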

Other observations

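Tests on depth, on the effect of clobetasol itself, on strong sites without a clobetasol peak, on counting chance and on separate partner peaks were chosen only after the result was seen. In the 1 Mb window with the most gained sites, chromosome 19, 18000001 to 19000000, 26 of 43 induced sites that were not repeat-like were retained. On chromosome 7, 100000001 to 101000000, 19 of 42 were, and on chromosome 16, 1 to 1000000, 25 of 37. Over the whole list, 58.3% of induced sites that were not repeat-like were retained. Differences between windows were not tested.

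The lower pileup with clobetasol has several candidate explanations. A shallower clobetasol pool is excluded, since the depth ratio was 1.21, and so are repeat-like sites as the source (median ratio 0.795 without them). Selection on the induced list is excluded too, with 0.816 when sites are picked in the clobetasol list. It was 0.823 with the 99 sites of that list lacking an induced peak ranked highest. A lower yield common to every site stays open: 1.14% of shared sites departed from 1 common factor of 0.735 on the excess (94 above, 25 below), but sites that fell furthest have no clobetasol peak and could not enter that test. Outside repeat-like sites at −log10 q of at least 20, 244 of 3803 peaks were lost. This was 2.38 times the 102.6 expected (95% range 84 to 122) at the factor of those peaks, 0.638. At 20 to 30, 210 of 1898 were lost against 96.5 expected (78 to 115), and at 30 or more, 34 of 1905 against 5.08 (1 to 10). Both windows thus lay above the range for 1 common factor. That range holds counting error alone, and the spread between libraries is not known. An effect of clobetasol on EGR1 binding cannot be told apart from a common yield or other differences between the pools, with 1 pool per group.

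The sites higher with clobetasol may be separate events or part of the spread between libraries. Of the 40, 57.5% were repeat-like, against 26.2% of all shared sites, which leaves 17. This does not settle whether repeats account for the set, since sites with many fragments pass the test more readily and tend to carry that label. Of the 2356 lower sites, only 1364 were outside repeat-like regions. A one-sided test adjusted over all shared sites passed 17 of the 40, only 4 of them outside repeat-like regions, so counting chance is excluded for the 17 as a set. The adjustment limits the share of false calls and does not exclude chance at each site. Chance stays open for the rest. Summits placed apart are excluded as an account of the whole set, with a median distance of 9 bp, but stay open for 5 of those 17 and 1 of those 4, with summits over 100 bp apart. An effect of clobetasol at the sites on chromosomes 14, 1 and 3 was not tested by other data.

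Neighbouring sites tended to change together. Over 1443 pairs of shared sites up to 10 kb apart, log2 ratios correlated at 0.132 across sites. This was above the range of −0.0849 to 0.0805 from 1000 random reassignments within 5 equal classes of induced pileup. Double counting may have caused this, but for 1193 pairs 1 to 10 kb apart with different partner peaks the correlation was also 0.132 (random range −0.0774 to 0.0897). Reassignments were not matched by control level, and whether clusters of repeat-like sites give the correlation was not tested. A regional component of the change is a hypothesis that these values leave open. It is small, and sites are not independent replicates.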
